A study of Mus musculus with 4 samples.

How the data were processed

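RNA was measured in 4 libraries of B220+CD43+ pro-B cells from mouse bone marrow, 2 from Cnot3 fl/fl and 2 from Cnot3 +/+ mice, all carrying RERTCre and all given tamoxifen. Per the labels' protocols, total RNA was extracted with a column kit, libraries were prepared with a stranded mRNA kit from Illumina and amplified by 15 cycles of PCR. Genotype and replicate number were taken from the sample labels. The series' design text describes the replicates as individual mice.

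The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.13, Bowtie2 2.2.3.0, Cufflinks 2.2.1 and Cuffnorm 2.2.1 and the genome build mm9. Their roles and order, the gene annotation, any filter, the use of strand and the scaling between libraries are not given in the sources used here. The authors deposited 1 table per library with an FPKM value (fragments scaled to transcript length and to the number of mapped fragments) for each of 23312 genes, per the file headers. They also deposited a comparison table with 1 FPKM value per genotype and a p-value and q-value per gene, per the file headers. Its FPKM values lay within 0.1% of the mean of the 2 libraries in 99.9% of genes. The locus column of these tables can merge neighbouring genes. The fold column of the comparison table was not used, because 1358 of its cells were not finite numbers and 13 lay beyond 100 in size.

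FPKM values are not counts, so no test on counts was run and the alternative planned for counts did not apply. Relative depth was estimated from genes under 0.3 FPKM in both libraries of a pair. The ratio of their values that held for the most genes within 0.5% was taken as the ratio of the value of 1 fragment. This ratio held for 9.44% to 13.2% of such genes, so it is an estimate, and the absolute depth stayed unknown.

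Values were transformed to log2(FPKM + 1), and 11017 genes with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). The test was two-sided, with genotype as the only term and Benjamini-Hochberg adjustment over the genes tested, and calls were made at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and 2.69 from the prior. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, whereas folds given in words are ratios of mean FPKM. Errors are SD over the libraries of a genotype unless named as standard errors.

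The test was run on simulated data with variances drawn from the fitted prior, with 200 of 11017 genes changed in 5 draws. Errors were drawn independently for each gene and library. It recovered 3.6% of genes changed by 0.5 on the log2 scale, 62.8% of those changed by 1, 91.2% of those changed by 2 and 98.4% of those changed by 3. With 3672 genes changed by 1, it recovered 92.1%, and 3.30% of its calls were false. Genes that vary together within a library were not simulated, so these shares are not error rates of the calls reported here.

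Before the data were examined, 27 gene lists were fixed for the tissue and the deleted gene, among them lists for other cells that the gate could hold. Lists with at least 5 tested members, 26 in all, were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. This called 2 lists higher and 3 lower. With an estimated correlation camera called 0 lists, and its adjusted p was 0.93 for each of those 5. It was also 0.93 for lists that were not called, such as glycolysis. This form of camera rests on the 2 residual degrees of freedom, so it had little power to call any list. A lost call there does not show that correlation between genes made the call. The estimated correlation was 0.24, 0.56 and 0.08 for the ribosomal, histone and early B-lineage lists. It was 0.55 for the interferon list and -0.04 for the later B-cell list. Above 0.01, the preset p-values can be too small. The fry test of whether a list's genes moved one way called 0 lists, and its test for change in either direction called 11. Members were also adjusted over the list alone.

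Genes were named by a rule fixed at the same time. It took Cnot3 and the other CCR4-NOT subunits, Trp53, and the 10 genes with the largest change in each direction among calls in which the genotypes' libraries did not overlap. From each list described, it added up to 4 members with the smallest p and any member past the threshold, and from the lists of other cells up to 3 of the most abundant. Small and structural RNA genes were left out of the naming, since a library of polyadenylated RNA does not measure them. There were 61 such genes among those tested, and 3 of them were called. A few genes that the rule takes are not reported here.

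Alternatives chosen at the same time were other pseudocounts (0.1 and 5), no filter on low values, a minimum mean of 5 FPKM, quantile normalization, rescaling to equal median ratios, eBayes without the trend and with a robust prior, the replicate number as a block, leaving out each library, leaving out small RNA genes, an estimated correlation for camera, and the authors' own calls. After the data were seen, a correction for transcript length and a minimum change of 2-fold were added. Transcript lengths came from the GENCODE annotation of mouse release M21, matched by symbol, as the median over a gene's transcripts. A length was found for 99.2% of tested genes and 100% of tested ribosomal protein genes. That annotation is on another genome build than mm9, so none of its coordinates were used. Figures were drawn with matplotlib 3.10.9.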

Results

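Messenger RNA was profiled by RNA sequencing in pro-B cells sorted from mouse bone marrow as B220+CD43+ cells. Pro-B cells are early B-lineage cells that rearrange their immunoglobulin heavy chain genes. The mice were C57BL/6 animals carrying RERTCre, a tamoxifen-inducible Cre recombinase, with either loxP-flanked (Cnot3 fl/fl) or wild-type (Cnot3 +/+) alleles of Cnot3. All mice received 1 mg tamoxifen on days 1, 2, 4 and 7 and were analysed on day 10. Each genotype had 2 libraries from individual mice. Cnot3 encodes a subunit of the CCR4-NOT complex, the main machinery that shortens the poly(A) tails of mRNAs. The comparison asked which transcripts differed in pro-B cells between induced Cnot3 fl/fl and Cnot3 +/+ mice.

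The deposited values were FPKM for 23312 genes per library and held no read counts, so the absolute depth was unknown. The spacing of the lowest values gave a relative depth of 0.955 and 1 for Cnot3 fl/fl replicates 1 and 2, and of 0.745 and 0.898 for Cnot3 +/+ replicates 1 and 2. Between 14684 and 15126 genes had a value above 0 in a library. Across the 11017 genes tested, the log2 values of the Cnot3 fl/fl libraries had a Pearson r of 0.980 with each other, and those of the Cnot3 +/+ libraries 0.963. The 4 pairs of libraries of different genotype gave 0.945 to 0.953. These correlations are across genes, which are not independent replicates. One library stood apart in sex-linked transcripts. In Cnot3 +/+ replicate 1 the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at 29.3, 16.0, 9.71 and 3.03 FPKM and Xist at 0.024 FPKM, whereas the other 3 libraries had Xist between 54.3 and 63.1 FPKM.

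The targeted gene itself did not differ between the genotypes at the level of the whole gene. Cnot3 was at 39.0 and 40.3 FPKM in the libraries labelled Cnot3 fl/fl and at 41.6 and 39.3 FPKM in the Cnot3 +/+ libraries, a log2 fold change of -0.03 with a standard error of 0.08 (limma, adjusted p = 0.83). The labels do not say which exons were flanked by loxP sites, so a value over the whole gene does not check the genotype labels, and the directions given here are those between libraries labelled Cnot3 fl/fl and Cnot3 +/+. In the files' mm9 locus column, Cnot3 spans chromosome 7 from 3596870 to 3629155. Whether these starts count from 0 or 1 is not given in the sources used here.

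Of the 11 CCR4-NOT subunits measured, 1 fell, none rose and 10 did not pass the test, and adjusted over the list alone the count was also 1. Cnot6, one of the deadenylase subunits, fell from 30.6 ± 0.784 FPKM to 20.3 ± 1.29 FPKM (SD, n = 2 each; log2 fold change -0.57, limma adjusted p = 0.040). In the authors' deposited table Cnot6 had a q-value of 0.069. The scaffold subunit Cnot1 was at 31.5 FPKM in Cnot3 fl/fl and 33.3 FPKM in Cnot3 +/+ libraries on average, and the catalytic subunits Cnot7 and Cnot8 had log2 fold changes of -0.10 and 0.22. The other subunits, Cnot2, Cnot4, Cnot6l, Rqcd1 (also known as Cnot9), Cnot10 and Cnot11, lay between -0.15 and 0.24. Among 25 other mRNA decay factors tested, the poly(A)-binding protein gene Pabpc1 fell by 0.63 on the log2 scale (adjusted p = 0.036) and the deadenylase gene Parn rose by 0.51 (adjusted p = 0.046). Adjusted over the list alone, 1 rose and 1 fell. Pan3 and Edc3 had log2 fold changes of -0.44 and 0.29 that did not pass (adjusted p = 0.056 and 0.077).

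**Figure D1:**
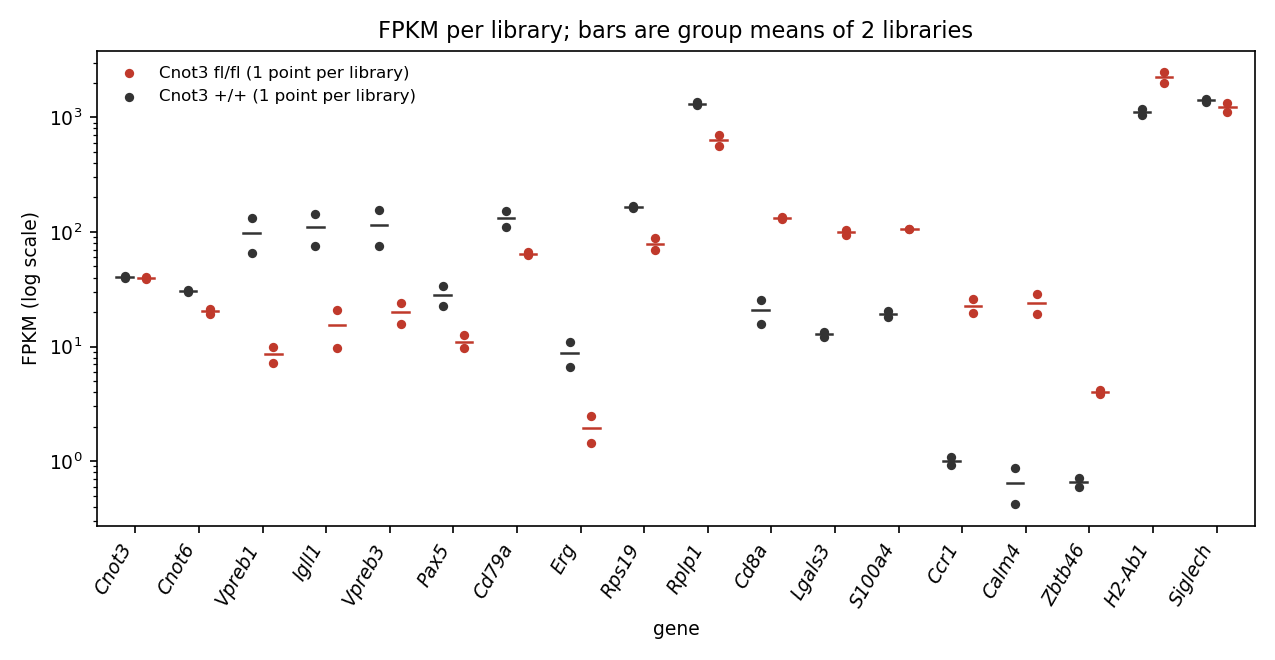
FPKM (log axis) of 18 genes in each library, with 1 point per library, Cnot3 +/+ in black and Cnot3 fl/fl in red, and a bar at each group's mean of 2 libraries. Cnot3 lies near 40 FPKM in all 4 libraries, Vpreb1, Igll1 and Vpreb3 are lower and Cd8a, Lgals3 and Ccr1 higher in both Cnot3 fl/fl libraries, and Siglech is above 1000 FPKM in all 4.

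Between the genotypes, 685 genes were higher and 361 lower in Cnot3 fl/fl libraries (limma, adjusted p under 0.05), of which 163 and 40 changed by at least 2-fold. With small and structural RNA genes left aside, the steepest falls included those in the surrogate light chain genes Vpreb1, Igll1 and Vpreb3, whose products pair with the heavy chain in the pre-B cell receptor. The largest rises were in the calmodulin-like genes Calm5 and Calm4, the chemokine receptor gene Ccr1 and the peptide hormone gene Sct. They were followed by the kallikrein gene Klk1b11, the galectin gene Lgals3, the myeloid receptor gene Pira6, the co-receptor gene Cd8a, and Lrrc15 and S100a4. The remaining genes in the list of steepest falls were Eps8l1, Rpl23a, Gfra2, Cplx2, Cadm1, the transcription factor gene Erg, and Lsm5, which encodes an RNA-binding Sm-like protein.

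Among these, Vpreb1 fell from 98.6 ± 47.1 FPKM in Cnot3 +/+ to 8.55 ± 1.89 FPKM in Cnot3 fl/fl libraries (SD, n = 2 each; log2 fold change -3.31, limma adjusted p = 0.029). Without Cnot3 +/+ replicate 2 its log2 fold change was -2.81. Igll1 was at 21.0 and 9.81 FPKM in Cnot3 fl/fl and at 75.6 and 143.8 FPKM in Cnot3 +/+ replicates 1 and 2, and Vpreb3 at 23.9 and 15.7 against 75.1 and 154.7 FPKM. Lgals3 rose 7.80-fold, from 12.8 ± 0.762 to 99.5 ± 7.05 FPKM (SD, n = 2 each; log2 fold change 2.87, limma adjusted p = 0.0033). Cd8a rose 6.38-fold, from 20.7 ± 7.06 to 132.1 ± 3.75 FPKM (SD, n = 2 each), and S100a4 5.53-fold, from 19.1 to 105.8 FPKM. Ccr1 rose from 1.01 to 22.7 FPKM and Calm5 from 0.177 to 17.5 FPKM. Sct was at 60.7 and 65.6 FPKM in Cnot3 fl/fl and at 2.70 and 9.09 FPKM in Cnot3 +/+ replicates 1 and 2, and Calm4 at 19.3 and 28.5 against 0.420 and 0.868 FPKM. Eps8l1 was listed at 0 in both Cnot3 fl/fl libraries and at 3.89 and 13.6 FPKM in the Cnot3 +/+ libraries. It lies on chromosome 7 from 4416343 to 4430844 (mm9), 0.787 Mb from Cnot3. Rpl23a, at 0.510 against 4.94 FPKM, and the falls of Gfra2, Cplx2, Cadm1, Erg and Lsm5 had log2 fold changes between -1.97 and -1.60.

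**Figure D2:**
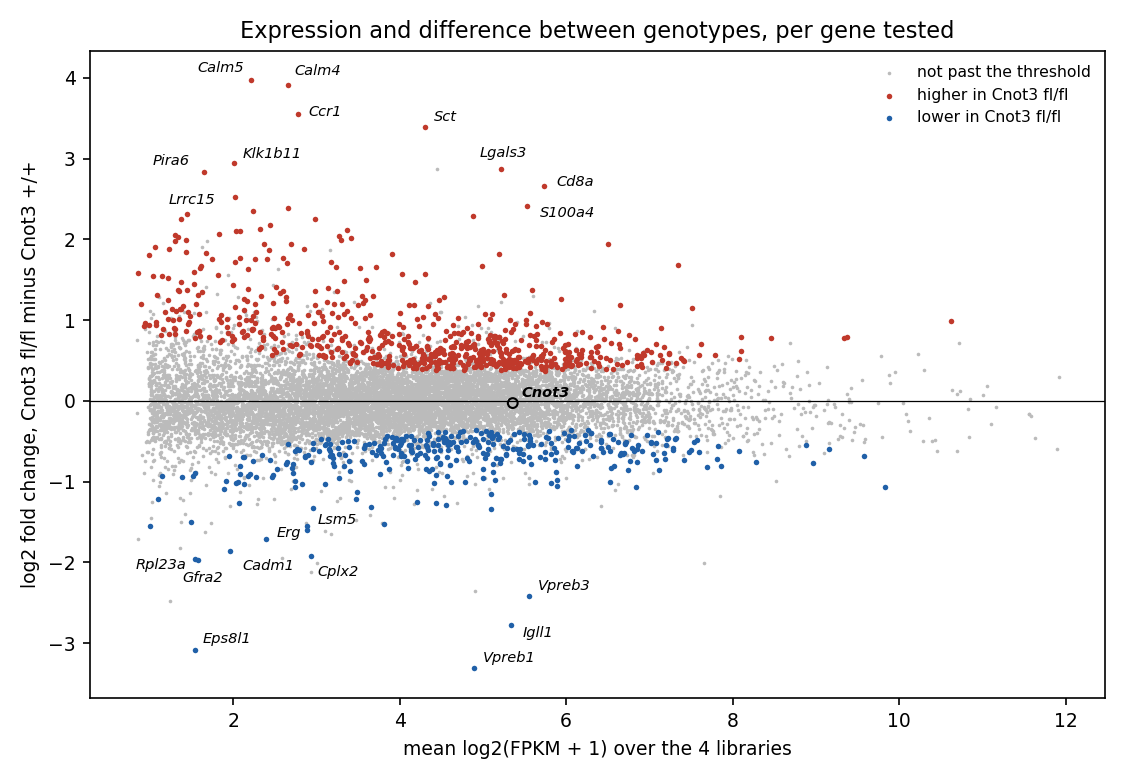
Log2 fold change (Cnot3 fl/fl minus Cnot3 +/+) against the mean log2(FPKM + 1) over 4 libraries, 1 point per tested gene, with red for genes higher and blue for genes lower at a limma adjusted p under 0.05 and grey for the rest. The 20 genes with the largest changes among the calls, 10 in each direction, and Cnot3 (circled, -0.03) are named. The 61 small and structural RNA genes among those tested are not drawn.

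In all 1046 calls both Cnot3 fl/fl libraries lay on the same side of both Cnot3 +/+ libraries. This held for 64.4% of all tested genes, where 33.3% is the chance for a single gene. Genes that vary together within a library shift this share together, so it does not test an effect of genotype. The unadjusted p was under 0.05 for 3722 genes, and an exact permutation test of a single gene in 2 against 2 libraries cannot go below p = 0.333. The authors' deposited table marked 801 genes as significant, 496 higher and 305 lower in Cnot3 fl/fl, and 731 of these were tested here. Both sets of calls come from the same 4 libraries and shared 342 higher and 143 lower genes, so this overlap is no independent support. Calls of single genes given here are those of limma unless the authors' table is named. Members of the gene lists that limma did not call but that table marked as significant included Ebf1, Rag1, Lig4, Klrd1, Gzmb, Csf1r, Dhx58, Oasl2, Cmpk2, Mzb1 and Igj. Of the 20 genes with the largest changes among the limma calls, Calm5 and Rpl23a were not significant in the authors' deposited table, with q-values of 0.32 and 0.085. With one library left out, the higher calls numbered 2 without Cnot3 fl/fl replicate 1, 6 without Cnot3 fl/fl replicate 2, 7 without Cnot3 +/+ replicate 1 and 18 without Cnot3 +/+ replicate 2, and the lower calls 0, 1, 13 and 13. With all genes above 0 in at least 1 library tested, 16296 in all, 4 genes were higher and 1 lower. Near-identical gene copies can share reads, so the values of Calm4 and Calm5, Klk1b11, Pira6, Vpreb1 and the ribosomal protein genes are uncertain in that respect.

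Genes of the B lineage were among those with lower values in Cnot3 fl/fl libraries. Of 15 measured genes of the pre-B cell receptor and its signalling, 5 fell, 2 rose and 8 did not pass the test. Those that fell included Vpreb1, Igll1, Vpreb3 and the receptor signalling gene Cd79a, which fell from 131.3 to 64.3 FPKM (limma adjusted p = 0.042). The kinase genes Lyn and Btk rose, with log2 fold changes of 0.57 and 0.61. Adjusted over the list alone, 6 fell and 2 rose, and the list as a set did not pass (camera, adjusted p = 0.46).

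Transcription factors of early B-cell development were lower as a set, with a median log2 fold change of -0.37 over 19 genes (camera, adjusted p = 0.0058). This call was lost with adjusted p = 0.93 with an estimated correlation. The gene at the median, Tcf4, is also in the panel of plasmacytoid dendritic cell genes used below, so the set does not measure B-lineage cells alone. In the test of single genes, 2 fell, 0 rose and 17 did not pass, and adjusted over the list alone 6 fell and 1 rose. Pax5, which commits cells to the B lineage, fell from 28.2 ± 8.05 to 11.1 ± 2.03 FPKM (SD, n = 2 each; log2 fold change -1.26, limma adjusted p = 0.045), and Erg fell from 8.78 to 1.96 FPKM. Ebf1, another lineage-specifying factor, was at 5.58 and 5.83 against 12.0 and 25.7 FPKM (adjusted p = 0.065), and Runx1 at 13.7 against 18.8 FPKM (adjusted p = 0.067). Of 14 genes of V(D)J recombination, which assembles the antigen receptor genes, 1 fell and 13 did not pass, also 1 when adjusted over the list alone. The one that fell was Hmgb1, a DNA-bending protein gene, at 8.09 against 14.6 FPKM (log2 fold change -0.78, adjusted p = 0.043). The recombinase genes Rag1 and Rag2 averaged 3.52 and 0.792 FPKM in Cnot3 fl/fl and 12.2 and 3.09 FPKM in Cnot3 +/+ libraries. Their limma adjusted p-values were 0.092 and 0.080. Per library, Rag1 was at 4.72 and 2.31 against 7.58 and 16.8 FPKM, and Rag2 at 1.26 and 0.321 against 2.43 and 3.75 FPKM. The ligase gene Lig4 had a log2 fold change of -0.70 (adjusted p = 0.091).

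Cytosolic ribosomal protein genes were lower in Cnot3 fl/fl libraries. Of 75 measured genes, 20 fell, 0 rose and 55 did not pass the test. Adjusted over the list alone, 40 fell and 0 rose. Both Cnot3 fl/fl libraries lay below both Cnot3 +/+ libraries in 64 of the 75 genes, and the median log2 fold change was -0.55. Rplp1 fell from 1315 ± 52.9 to 629.6 ± 101.3 FPKM (SD, n = 2 each; log2 fold change -1.07, limma adjusted p = 0.040), Rps19 from 164.7 to 78.6 FPKM and Rps2 from 123.3 to 68.8 FPKM. Rpl22, Rpl13, Rpl15, Rpl37, Rps26, Rplp2, Rpl18, Rpl34, Rps18, Rps24, Rps7, Rpl14, Rps15a, Rpl29 and Rpl35a also fell, with log2 fold changes between -0.90 and -0.47. As a set the genes ranked lower than the other genes tested (camera, adjusted p = 4.9e-15), a call lost with adjusted p = 0.93 with an estimated correlation.

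Genes of energy metabolism went both ways. In 35 measured genes of mitochondrial oxidative phosphorylation, 3 rose, 4 fell and 28 did not pass, with 5 and 6 when adjusted over the list alone. Ndufa9, Sdha and Uqcrc1, which encode subunits of complexes I, II and III, rose with log2 fold changes of 0.54, 0.55 and 0.45, whereas the small subunit genes Cox5a, Cox6c, Ndufa4 and Ndufa1 fell, with log2 fold changes between -0.66 and -0.55. Of 17 glycolysis genes 3 rose, 0 fell and 14 did not pass, with 5 and 0 when adjusted over the list alone. These were the phosphofructokinase genes Pfkp and Pfkl and the hexokinase gene Hk2, at 45.2, 30.6 and 5.34 FPKM against 27.1, 20.3 and 2.99 FPKM. The lactate exporter gene Slc16a3 had a log2 fold change of 0.76 (limma adjusted p = 0.064). Neither list passed as a set (camera, adjusted p = 0.48 and 0.43). Of 23 ribosome biogenesis genes linked to Myc, Npm1, which encodes a nucleolar chaperone, fell (log2 fold change -0.54, adjusted p = 0.045) and 22 did not pass, with 0 when adjusted over the list alone. Pes1, Wdr43 and Tcof1 had log2 fold changes of 0.36, 0.26 and 0.25 (adjusted p = 0.075, 0.082 and 0.098), and the list's camera adjusted p was 0.48.

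**Figure D3:**
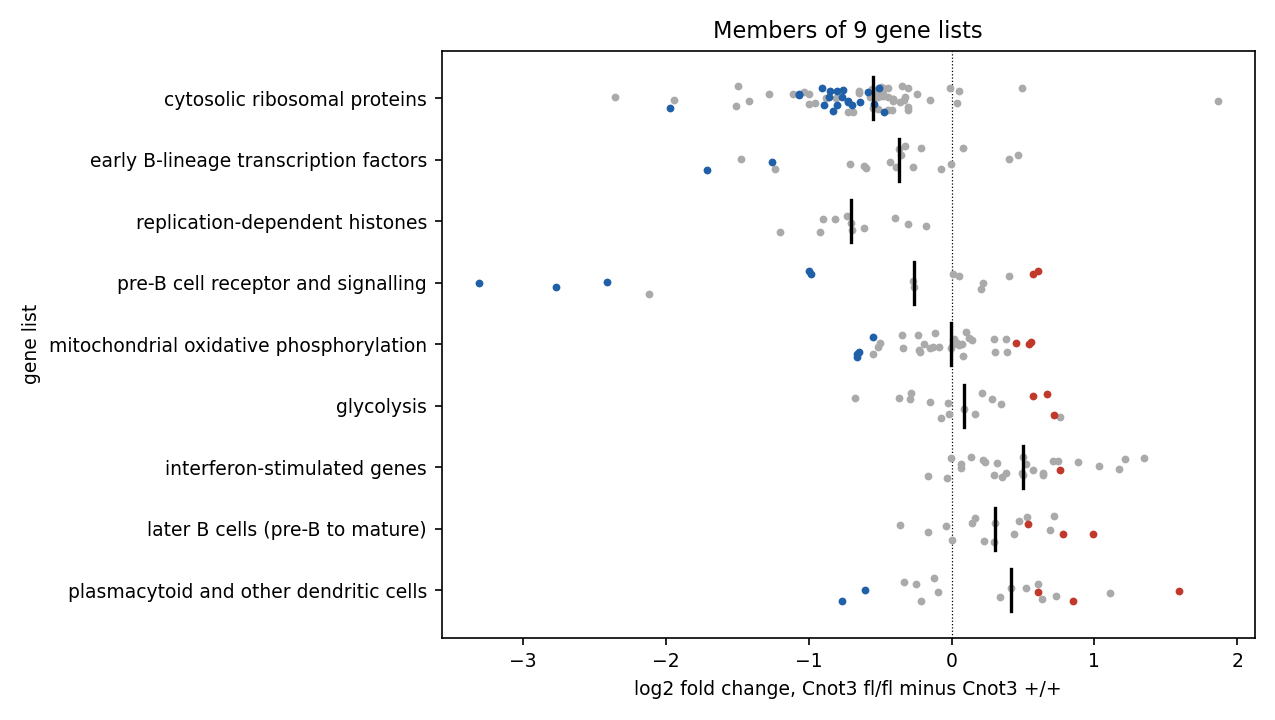
Log2 fold change (Cnot3 fl/fl minus Cnot3 +/+) of each tested member of 9 gene lists, with 1 point per gene, red for genes higher and blue for genes lower at a limma adjusted p under 0.05, grey for the rest, and a black bar at each list's median. The medians are -0.55 for the ribosomal proteins, -0.70 for the histones and 0.50 for the interferon-stimulated genes.

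Transcripts of other bone marrow cells were abundant in all 4 sorted libraries. The plasmacytoid dendritic cell genes Siglech, Cox6a2 and Klk1 averaged 1223, 381.6 and 650.0 FPKM in Cnot3 fl/fl and 1413, 655.6 and 483.5 FPKM in Cnot3 +/+ libraries, against 64.3 and 131.3 FPKM for Cd79a. Of 17 plasmacytoid and other dendritic cell genes, 3 rose, 2 fell and 12 did not pass, with 8 and 2 when adjusted over the list alone. Zbtb46, a transcription factor of classical dendritic cells, rose from 0.657 to 4.00 FPKM (log2 fold change 1.59, limma adjusted p = 0.024), the receptor gene Clec9a from 29.5 to 53.6 FPKM and Tlr7 from 52.1 to 79.6 FPKM. Cox6a2 fell (log2 fold change -0.77, adjusted p = 0.049), as did the lectin gene Clec10a (log2 fold change -0.60, adjusted p = 0.045). Among 19 neutrophil and monocyte genes, the integrin gene Itgam and the granule protease genes Ctsg and Elane rose, with log2 fold changes of 0.68, 1.35 and 1.04, none fell in limma and 16 did not pass. The authors' table marked 5 as higher and 1 as lower, Cebpa, which was named after its values were seen. Adjusted over the list alone 5 rose. Csf1r was at 3.67 against 1.2 FPKM (adjusted p = 0.051), the abundant Cybb at 328.1 against 257.4 FPKM, and S100a9 and S100a8 at 84.8 and 49.7 against 83.1 and 49.8 FPKM. The dendritic list and the neutrophil and monocyte list each had a camera adjusted p of 0.31. The median of the neutrophil and monocyte list was 0.27 without Cnot3 fl/fl replicate 2 and 0.35 without Cnot3 +/+ replicate 2. It was 0.18 without Cnot3 fl/fl replicate 1 and -0.06 without Cnot3 +/+ replicate 1.

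Among 24 genes of T, NK and innate lymphoid cells, Cd8a and Cd5 rose and 22 did not pass, with 2 and 0 when adjusted over the list alone (camera, adjusted p = 0.56). The list's median was 0.36 without Cnot3 fl/fl replicate 2 and -0.21 without Cnot3 fl/fl replicate 1. Cd5 rose from 4.64 to 11.2 FPKM (log2 fold change 1.10, limma adjusted p = 0.045). The natural killer receptor gene Klrd1 was at 130.6 against 70.6 FPKM (adjusted p = 0.062) and the granzyme gene Gzmb at 21.5 against 11.4 FPKM (adjusted p = 0.12). The most abundant members, Ccl5, Cd4 and Nkg7, were at 338.6, 152.9 and 129.8 FPKM in Cnot3 fl/fl and 384.3, 213.3 and 128.5 FPKM in Cnot3 +/+ libraries and did not pass. Genes of later B cells, from the pre-B to the mature stage, ranked higher as a set, with a median log2 fold change of 0.30 over 17 genes (camera, adjusted p = 0.042). This call was lost with adjusted p = 0.93 with an estimated correlation, although the correlation estimated for this list was -0.04, below the preset 0.01. Without Cnot3 +/+ replicate 1, the library with Y-linked transcripts, the median was 0.23. With no filter on low values the camera adjusted p was 0.22 with a median of 0.30. The 3 members that rose act in antigen presentation on MHC class II, which dendritic cells share with B cells. Ciita, its master regulator, rose from 24.9 to 36.6 FPKM, H2-Ab1 from 1114 to 2225 FPKM and H2-Eb1 from 493.1 to 847.4 FPKM. The other 14 did not pass, among them H2-Aa, Cd74 and Cxcr5 with log2 fold changes of 0.72, 0.30 and 0.48. Ms4a1 and Cd22, members named after their values were seen, had -0.36 and 0.15 (limma adjusted p = 0.063 and 0.49). The log2 fold change was positive in 14 of the 17 genes and negative in 3. Adjusted over the list alone, 7 rose and 1 fell.

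In the remaining lists of other cells, the syndecan gene Sdc1, a plasma cell marker that pre-B cells also carry, fell from 38.1 to 18.6 FPKM (limma adjusted p = 0.036), as 1 of 8 plasma cell genes, and also alone when adjusted over the list alone. Mzb1, Igj and Tnfrsf17 did not pass (adjusted p = 0.25, 0.50 and 0.50). Of 10 stem and progenitor cell genes, the transcription factor genes Meis1 and Hoxa9 fell, from 5.27 to 2.29 and from 4.89 to 1.88 FPKM, none rose and 8 did not pass. The receptor gene Flt3 was at 202.0 against 131.6 FPKM (adjusted p = 0.060), and Ly6a, Satb1 and Notch1 had log2 fold changes of 0.50, 0.38 and -0.38. Adjusted over the list alone, 3 rose and 2 fell. The transferrin receptor gene Tfrc fell (log2 fold change -0.48, adjusted p = 0.045), as 1 of 5 erythroid and megakaryocyte genes, where Hba-a1, Hbb-b1 and Car2 averaged 16.4, 12.6 and 12.2 FPKM in Cnot3 fl/fl libraries and did not pass, and adjusted over the list alone 1 fell. The mast cell protease gene Cma1 rose from 1.52 to 4.25 FPKM (adjusted p = 0.042), and Prg2 was at 12.2 against 9.60 FPKM. These were the 2 genes of basophils, mast cells and eosinophils with enough expression to be tested, and adjusted over the list alone 1 rose. None of 9 genes of stroma, endothelium and macrophages passed in limma, also when adjusted over the list alone, and 0 were marked in the authors' table. At an unadjusted p under 0.05, 1 was higher and 1 lower. Pecam1, Cdh5, Kdr and Cd163 had log2 fold changes of -0.19, -0.44, 0.41 and 0.43, and that list's median and mean were positive while its camera test pointed down (adjusted p = 0.95). The camera adjusted p was 0.48 for plasma cells, 0.87 for stem and progenitor cells and 0.31 for erythroid cells and megakaryocytes. The plasma cell median was -0.82 without Cnot3 +/+ replicate 1 and 0.37 without Cnot3 +/+ replicate 2.

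Interferon-stimulated genes ranked higher in Cnot3 fl/fl libraries as a set, with a median log2 fold change of 0.50 over 27 genes (camera, adjusted p = 0.0030). The call was lost with adjusted p = 0.93 with an estimated correlation. Without Cnot3 +/+ replicate 1, the library with Y-linked transcripts, the adjusted p was 0.062 and the median 0.20. The median was 0.31 without Cnot3 fl/fl replicate 1 and 0.30 with a pseudocount of 5. Xaf1 rose from 6.66 to 11.9 FPKM (log2 fold change 0.76, limma adjusted p = 0.046), and 26 did not pass, with 0 when adjusted over the list alone. Dhx58, Oasl2 and Cmpk2 were at 38.5, 45.0 and 16.6 FPKM against 18.9, 20.5 and 10.4 FPKM (adjusted p = 0.064, 0.077 and 0.070).

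Trp53, which encodes the tumour suppressor p53, was at 65.4 and 71.9 FPKM in Cnot3 fl/fl and 62.9 and 49.6 FPKM in Cnot3 +/+ libraries (log2 fold change 0.29, limma adjusted p = 0.21). Of 23 p53 target genes 2 rose, none fell and 21 did not pass, with 4 higher and 1 lower when adjusted over the list alone. Phlda3 was at 3.80 and 3.13 FPKM in Cnot3 fl/fl and at 0.611 and 1.35 FPKM in Cnot3 +/+ libraries (log2 fold change 1.19, adjusted p = 0.049), and Apaf1, which forms the apoptosome, rose from 16.3 to 21.9 FPKM (log2 fold change 0.41, adjusted p = 0.046). Sesn2 and Dcxr had log2 fold changes of 0.62 and 0.63 (adjusted p = 0.063 and 0.058). None of the 14 BCL2 family genes tested passed in limma, singly or when adjusted over the list alone, and 0 had an unadjusted p under 0.05, whereas the authors' table marked Bbc3 as higher (q-value 0.027). The pro-apoptotic Bbc3, Bmf and Bid had log2 fold changes of 0.73, 0.56 and 0.22, and the anti-apoptotic Bcl2l1 had -0.45 (adjusted p between 0.19 and 0.23). Neither list passed as a set (camera, adjusted p = 0.46 and 0.43). In the IL-7 receptor pathway, which sustains pro-B cells, Stat5a rose from 25.4 to 35.2 FPKM (log2 fold change 0.46, adjusted p = 0.043) and 15 of 16 genes did not pass, with 1 higher when adjusted over the list alone. Jak1, Il2rg and Ccnd3 had log2 fold changes of 0.40, 0.35 and -0.67, and the list's camera adjusted p was 0.87.

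Genes of cell division gave different calls in limma and in the authors' table. None of 28 DNA replication genes and none of 27 mitosis genes passed in limma, singly or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. The authors' table marked Rrm2 as lower and Mcm6 as higher in the first list, and Top2a, Cdk1, Birc5, Kif11 and Ube2c as lower in the second. Kif11 and Ube2c were named after their values were seen. The S-phase genes Rrm2, Tyms, Cdt1 and Mcm6 had log2 fold changes of -0.91, -0.62, 0.49 and 0.73. Top2a was at 23.2 and 17.1 FPKM in Cnot3 fl/fl and 19.8 and 58.2 FPKM in Cnot3 +/+ replicates 1 and 2. In the same order, Birc5 was at 15.6 and 10.9 against 13.6 and 39.3 FPKM. Cdk1 was at 5.49 and 4.31 against 5.03 and 15.0 FPKM, and Ccnb1 at 1.26 and 0.961 against 1.24 and 2.77 FPKM. Birc5, Cdk1 and Ccnb1 had log2 fold changes of -0.78, -0.74 and -0.47, with the highest value in Cnot3 +/+ replicate 2. The mitosis list was not called (camera, adjusted p = 0.31). Its median was -0.84 without Cnot3 +/+ replicate 1 and 0.31 without Cnot3 +/+ replicate 2. The estimated correlation between its genes was 0.98, so these medians follow the lone Cnot3 +/+ library kept. The DNA replication list was not called either (camera, adjusted p = 0.48), with an estimated correlation of 0.93. Its median was -0.49 without Cnot3 +/+ replicate 1 and 0.15 without Cnot3 +/+ replicate 2. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were lower as a set in all 11 genes tested (median log2 fold change -0.70, camera adjusted p = 0.010), a call lost with adjusted p = 0.93 with an estimated correlation. None passed in limma singly or when adjusted over the list alone, 4 were lower at an unadjusted p under 0.05, and the authors' table marked Hist3h2a as lower. Hist2h2ac, Hist1h4c, Hist1h2bg and Hist3h2a had limma adjusted p-values of 0.067, 0.077, 0.086 and 0.13. The set's adjusted p was 0.19 without Cnot3 +/+ replicate 2 and 0.37 with a minimum mean of 5 FPKM, with medians of -0.38 and -0.40. The size of the fall depended on the pseudocount, with medians of -1.28 at 0.1 and -0.28 at 5, and the median was -0.35 with no filter on low values. Of 29 immediate-early and other short-lived mRNAs and 17 genes of the integrated stress and unfolded protein responses, none passed in limma, also when adjusted over the list alone. At an unadjusted p under 0.05, 1 of the first list was lower and 1 of the second higher. The authors' table marked Gadd45b and Dusp2 as lower and Nr4a1 as higher in the first, and Sesn2 as higher in the second, with Dusp2 and Nr4a1 named after their values were seen. Gadd45b, Gadd45a, Mafk and Egr3 had log2 fold changes of -0.76, -0.65, -0.42 and 0.23, and the chaperone genes Hsp90b1 and Pdia4 and the transcription factor gene Xbp1 had -0.34, -0.27 and -0.30. The camera adjusted p was 0.58 for the short-lived mRNAs and 0.70 for the stress responses. The median of the short-lived mRNAs was -0.67 without Cnot3 fl/fl replicate 2 and -0.68 without Cnot3 +/+ replicate 1. It was 0.62 without Cnot3 fl/fl replicate 1 and 0.36 without Cnot3 +/+ replicate 2. In 28 of 29 of these genes replicate 2 was higher than replicate 1 in both genotypes. Leaving out 1 library unbalances the replicate numbers, so these medians do not measure a genotype difference. The camera adjusted p was 0.58 for the CCR4-NOT subunits, 0.53 for the other decay factors and 0.31 for V(D)J recombination. The V(D)J median was -0.25 without Cnot3 +/+ replicate 1 and -0.09 without Cnot3 +/+ replicate 2.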

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

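The correction for transcript length and the minimum change of 2-fold were chosen after seeing the data. Of the 162 named genes, 80 were past the threshold. Of those 80, 79 and 76 stayed past the threshold at pseudocounts of 0.1 and 5, 76 with quantile normalization, 80 with median rescaling, 76 with the robust prior and 78 of 79 with the length correction. Without the variance trend 23 stayed past it, with the replicate block 59, with no filter on low values 3, and with 1 library left out between 0 and 6. The count of higher genes was 4 and of lower genes 1 with no filter, where 16296 genes were tested, and 242 and 69 without the variance trend. The cause was not tested. Among calls of at least 2-fold, 163 genes were higher and 40 lower. With 1 library left out, the genes called higher numbered 2 to 18 and lower 0 to 13, the lists called higher 0 to 4 and lower 2 to 8. These fits have 1 residual degree of freedom per gene and assume that the lone library varies like the other genotype. With no filter, 1 list was higher, and with an estimated correlation 0 lists were higher and 0 lower. The ribosomal protein list and the early B-lineage factor list were called lower in all 15 refits at the preset correlation. The length-corrected counts were 737 higher and 465 lower, and the authors' own calls numbered 496 and 305. The files hold no counts, so the alternative for counts was not run, and depth is known only in relative terms.

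Labels give replicates 1 and 2 in both genotypes without tying the numbers to a shared day or litter. With the replicate number as a block, 456 genes were higher and 270 lower, 612 of them shared with the main calls, and no call of a list changed. Across 11017 genes the replicate differences of the genotypes had a Pearson r of 0.14.

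Cnot3 ranged from -0.067 to 0.012 (log2 fold change) with 1 library left out. Other genes that crossed 0 on leaving out 1 library were not past the threshold in any of those fits. Their ranges were -0.21 to 0.00082 for Cnot7, -0.21 to 0.055 for Rqcd1, -0.12 to 0.033 for Cnot10, -1.50 to 0.0096 for Top2a, -0.29 to 0.33 for Nkg7, -0.34 to 0.45 for S100a9, -0.35 to 0.27 for S100a8, -0.63 to 0.090 for Car2, -1.10 to 0.18 for Hbb-b1, -0.27 to 1.21 for Prg2, -1.35 to 0.21 for Tnfrsf17, -2.58 to 0.38 for Igj and -0.25 to 1.25 for Ly6a. Siglech was at 0.093 with quantile normalization and S100a8 at 0.019 with the length correction. List medians that crossed 0 in the same way ranged from -0.21 to 0.031 for other mRNA decay factors, -0.15 to 0.040 for the IL-7 receptor pathway, -0.49 to 0.15 for DNA replication, -0.84 to 0.31 for mitosis, -0.68 to 0.62 for immediate-early and other short-lived mRNAs, -0.40 to 0.18 for the integrated stress response, -0.11 to 0.027 for oxidative phosphorylation, -0.015 to 0.19 for glycolysis, -0.049 to 0.16 for ribosome biogenesis, -0.21 to 0.36 for T and NK cells, -0.057 to 0.35 for neutrophils and monocytes, -0.82 to 0.37 for plasma cells and -0.32 to 0.62 for stroma. At a minimum mean of 5 FPKM the medians were 0.022 for the IL-7 receptor pathway and 0.0016 for DNA replication. The cause was not tested for any of these.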

Other observations

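In this part, the tests of the B-lineage pattern were chosen only after its result was seen. Several further genes rose with Lgals3 and S100a4 and were picked after their values were seen. The fractalkine receptor gene Cx3cr1 was at 10.2 and 10.9 FPKM in Cnot3 fl/fl and 1.27 and 1.89 FPKM in Cnot3 +/+ libraries (log2 fold change 2.18, limma adjusted p = 0.019), and the myeloid lectin gene Cd33 at 19.8 and 21.3 against 3.45 and 4.57 FPKM. Actn1, an actin crosslinker gene, was at 64.9 and 63.7 against 10.6 and 14.4 FPKM, and Cd8b1 rose alongside Cd8a, at 166.9 and 187.6 against 33.4 and 61.0 FPKM. Dntt, which adds nucleotides at V(D)J junctions in pro-B cells, was also picked after its values were seen. It was at 243.8 and 254.7 against 215.9 and 217.3 FPKM (limma adjusted p = 0.18), and did not fall as the surrogate light chain genes did. Which cells its transcripts came from was not tested.

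Immediate-early and other short-lived mRNAs followed the replicate number and not the genotype. In 28 of 29 such genes replicate 2 was higher than replicate 1 in both genotypes, with median differences of 1.34 (log2) in Cnot3 fl/fl and 1.26 in Cnot3 +/+ mice. Over all genes tested, 27.2% were higher in replicate 2 in both genotypes. No explanation of this difference was tested.

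Some B-lineage genes fell, while some dendritic and myeloid genes, such as Zbtb46, Clec9a, Itgam and Ctsg, rose and others, Cox6a2 and Clec10a, fell. The pre-B cell receptor list, the dendritic list and the neutrophil and monocyte list did not pass as sets (camera, adjusted p = 0.46, 0.31 and 0.31). More plasmacytoid dendritic cells would raise their abundant genes. The 5 most abundant, Bst2, Ly6d, Siglech, Klk1 and Cox6a2, had log2 fold changes of -0.16, -0.62, -0.21, 0.42 and -0.77. Their median was -0.21 (standard error over these genes 0.21), and Cox6a2 fell. These genes did not rise together. Bst2 is also in the interferon list, and the standard error does not measure the spread between mice, so a small change in the share of these cells stays open. Without Cnot3 +/+ replicate 1, the library with Y-linked transcripts, the median of the early B-lineage factors was -0.51 (standard error over genes 0.16). The lower median thus did not rest on that library. Only 1 Cnot3 +/+ library was left in this comparison, so it cannot decide whether sex plays a part. Vpreb1, Vpreb3 and Igll1 fell further than 9 pan-B genes by a difference of -2.16 in log2 fold change (standard error 0.46). They are among the steepest falls, so this difference does not exclude a smaller share of all B-lineage cells, which stays open. A different mixture of B-lineage stages, other dendritic or myeloid cells passing the B220+CD43+ gate, and changed expression within pro-B cells also stay open as hypotheses. Of the 9 pan-B genes 6, and of the 10 plasmacytoid dendritic cell genes 8, are also in lists fixed for the report.

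Cytosolic ribosomal protein genes have short transcripts, with a median length of 632 nucleotides against 1332 for all genes tested, so a bias against short transcripts could lower them. Among 10000 random lists of 75 genes matched on transcript length and expression, 0% had a median as low as -0.55, and 95% of the lists lay between -0.14 and 0.05. These lists were drawn gene by gene, whereas the ribosomal protein genes had an estimated correlation of 0.24. The interval is thus a spread over genes and not between mice. Fold change and length had a Spearman rho of 0.01 between genotypes. For replicate 2 minus 1 it was -0.12 within Cnot3 fl/fl and -0.14 within Cnot3 +/+. Scaling between libraries was also tested, and with quantile normalization the median stayed at -0.55. Both tests argue against these explanations as the whole cause, while reads shared with the many processed pseudogenes of this family and a different mixture of cells stay open. A lower level of ribosomal protein mRNAs in Cnot3 fl/fl cells may therefore be followed up as a hypothesis.

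Eps8l1, listed at 0 in both Cnot3 fl/fl libraries, lies 0.787 Mb from Cnot3, so a segment of chromosome 7 carried along with the fl/fl allele is a candidate explanation. Of 55 tested genes within 5 Mb of Cnot3, 8 were called (14.5%), against 9.47% elsewhere, an odds ratio of 1.63 with a 95% confidence interval of 0.66 to 3.49 (Fisher's exact test, p = 0.24). Beside Eps8l1, which prompted the test, they were Pira6, Pira11, Lilra6, Myadm and Mboat7, which rose, and Ndufa3 and Clcn4-2, which fell. Pira11 and Lilra6 are listed with the same start, 3788411, so the called genes are not all independent, as the test takes them to be. The interval spans 1, so a higher share of calls near Cnot3 was not shown. Such a share would also not separate the candidate explanations, so a linked segment and an effect of the deletion cannot be told apart for these genes.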
